A study of Homo sapiens with 4 samples.

How the data were processed

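Gene expression of 4 samples of Jurkat cells was measured on 4 single-colour oligonucleotide arrays, 1 per group, from total RNA labelled with biotin. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and biotinylated cRNA was prepared from 6 ug of total RNA by the manufacturer's standard protocol. The groups were taken from the sample titles and the series' design text: a control line and an shIKKE line, each without (solvent) or with PMA at 10 ng/ml and ionomycin at 0.5 uM for 3 h. The design text calls the construct of the control line a control hairpin and the titles call it a vector, so it is called the control line here. The treatment text is the same for all 4 samples, and the titles alone tell the stimulated from the solvent samples.

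The deposited table holds 1 intensity per probe set and array, the MAS5 signal on a linear scale per the submitters' processing notes. The version of MAS5, its scaling target and any filter are not given in the sources used here. From the values, the mean after trimming 2% at each end was 500.07 on each of the 4 arrays, so the arrays had been scaled to one target. Such scaling equalises the mean of the brighter probe sets and leaves the dim end free, and the median signal ranged from 48.8 to 69.1 between arrays. MAS5 combines perfect-match and mismatch probes, which spreads low signals widely, and detection calls were not used here. The table had 0 columns that were left out.

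Of the probe sets, 62 are array controls and were left out of gene-level work. Gene names came from the platform annotation, with 41091 probe sets having 1 gene symbol, 1801 several and 11721 none; probe sets with several symbols or none were not named. Of those with 1 symbol, 41037 matched the RefSeq gene table of assembly GRCh38.p14 by gene ID, which replaced 0 symbols. No genome build is named in the files, so no coordinates are given. Values were used as log2 of the signal plus a pseudocount of 14.1, the 25th percentile of all signals of the 4 arrays. Probe sets were kept where the highest of the 4 arrays reached 56.4, the median of all signals, which left 26218 probe sets of 13717 genes. Each gene was represented by its probe set with the highest mean log2 value. Brighter and dimmer genes are those above and below the median of the mean level.

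Comparisons of single arrays were differences of log2 values, and a gene was counted where it differed by at least 2-fold (log2 of 1). They have no test, because there is 1 array per group. The 5 differences were stimulation in each line, the shIKKE line over the control line in each treatment, and the difference of the lines' responses. Average effects of stimulation and of the line were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, additive model of line and stimulation over all 4 arrays), two-sided, with Benjamini-Hochberg adjusted p at most 0.05. The model leaves 1 residual degree of freedom, which is the difference between the lines' responses and not an error between replicates of a group. The labels do not say whether the samples came from separate cultures on separate days. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

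The gene lists, the rule for the genes named, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. There were 20 lists: immediate early transcription factors, cytokines and chemokines, NFAT targets, NF-κB targets, interferon-stimulated genes, activation and checkpoint surface molecules, T cell receptor and proximal signalling, MAPK feedback regulators, NFAT and calcineurin components, IKK-related kinases and partners, cell cycle, apoptosis regulators, cholesterol synthesis, glycolysis, endoplasmic reticulum stress and heat shock, housekeeping genes, and markers of B cells, of myeloid cells, of natural killer and cytotoxic cells, and of erythroid and epithelial cells. Members without a named probe set past the filter are not analysed here. For each list and comparison, the median log2 change was placed as a percentile among the medians of 10000 random lists of the same size matched on mean level in 20 bins, which describes these arrays and gives no p-value. A median was taken to stand apart outside the central 95% of the random lists, a limit set with the code and not in the plan. For limma, counts are also given adjusted over the list alone.

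Genes were named by this rule, among genes past the filter with 1 symbol. For stimulation and for the lines, the 10 with the largest increase and the 10 with the largest decrease by the mean of both differences were named, among genes at least 2-fold in the same direction in both. For the difference of responses, the 8 highest and the 8 lowest were named, among genes at least 2-fold stimulated either way in at least 1 line. From each list, up to 4 members with the largest change in the comparison described were named, and a fixed set of well-known genes was always named, such as IKBKE, TBK1, IL2, TNF and GAPDH. Members of small counts outside the rule were named after their values were seen. Genes on the Y chromosome and XIST were left out of the names.

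The limma step was tested on simulated arrays for the average stimulation effect, with 13717 genes at their real mean levels, noise set from the spread of the response differences, and 50 genes changed at each size. It recovered 0% of the genes changed by a log2 of 1, 10% at 2, 72% at 3 and 92% at 4, with 4 false calls among the unchanged genes. With an intensity trend in the prior it recovered 40%, 82%, 94% and 92%, with 6 false calls. The simulation gave genes of the same level the same spread of noise, which the trend fit assumes. Its recovery was thus built in and does not speak for its calls on real genes. The list step placed a planted shift of 1 in 16 genes at percentile 100 with a median of 1.10, and called 7 of 100 unchanged random lists apart. A low share of such calls was built in, because these lists were random genes with independent noise. The noise of the simulation includes any true difference between the lines' responses, so it bounds neither the real noise nor the number of calls made by chance.

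The alternatives were no pseudocount or one at the median of all signals, no filter or one at the 75th percentile, quantile or cyclic loess normalization between arrays, the median of a gene's probe sets or only probe sets specific to 1 gene by their name, thresholds of 1.5-fold and 3-fold, an adjusted p of 0.1, a 2-fold minimum beside the adjusted p, and an intensity trend in limma's prior. The stimulated control array over the solvent array of the shIKKE line was added after the data were seen. These 2 arrays differ in line as well as in treatment, so their difference is not an effect of stimulation alone.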

Results

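Gene expression was measured in Jurkat cells, an established human T cell leukaemia line, carrying either a control construct (the control line) or a short hairpin RNA against IKKε (the shIKKE line). IKKε, encoded by IKBKE, is a kinase related to TBK1 that acts in NF-κB and interferon signalling. Each line was treated for 3 h with solvent or with 10 ng/ml PMA and 0.5 uM ionomycin. PMA activates protein kinase C and ionomycin lets calcium into the cell, and together they bypass the T cell receptor. This gave 4 groups of 1 array each, so that no difference between single arrays has a replicate check, and such differences are given as values without a p-value. The median signal was 48.8 in the control line with solvent, 59.8 in the control line with stimulation, 49.6 in the shIKKE line with solvent and 69.1 in the shIKKE line with stimulation, so that it was higher on both stimulated arrays. The 5′ to 3′ signal ratio of the ACTB control probe sets, a measure of RNA integrity, was 0.244, 0.401, 0.339 and 0.266 in the same order, and that of GAPDH lay between 1.04 and 1.17. Log2 changes below are of the signal plus 14.1, which understates the change of dim genes, and cover 13717 genes.

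The targeted gene was lower in the shIKKE line by its brighter probe set in both treatments. That probe set of IKBKE read 340 in the control line and 180 in the shIKKE line with solvent, a log2 difference of -0.86. With stimulation it read 520 and 248, a log2 difference of -1.03. A second, dimmer IKBKE probe set read 218 and 287 with solvent (log2 0.38) and 311 and 280 with stimulation (log2 -0.14), so the 2 probe sets differed in direction with solvent. The median of both probe sets gave log2 differences of -0.24 and -0.59. TBK1, the closest relative of IKBKE, read 1664 and 2216 with solvent and 1932 and 2032 with stimulation in the control and shIKKE lines. Among 15 measured IKK-related kinases and partners, 2 were at least 2-fold lower in the shIKKE line with solvent and 2 with stimulation, and none was higher. These were CYLD (log2 -1.23) and OPTN (log2 -1.27) with solvent, and IKBKE and the TBK1 adaptor TBKBP1 (log2 -2.01) with stimulation. The median of the list lay at percentile 44.4 of random lists matched on mean level with solvent (log2 -0.11) and at percentile 3.06 with stimulation (log2 -0.19).

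**Figure D1:**
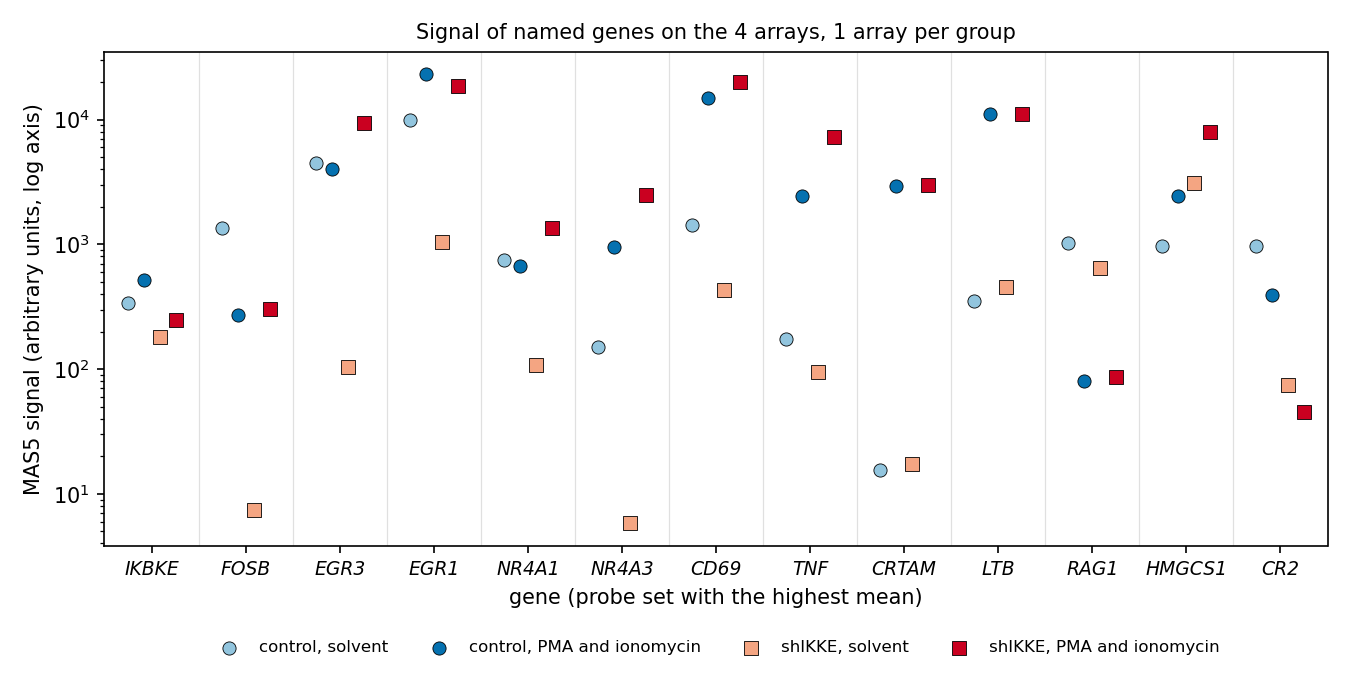
MAS5 signal (arbitrary units, logarithmic vertical axis) of 13 named genes on the 4 arrays; circles are the control line and squares the shIKKE line, pale with solvent and dark with PMA and ionomycin, 1 array per group without error bars. CRTAM and LTB lay at nearly the same levels in both lines, whereas FOSB and EGR3 read 1364 and 4526 in the control line with solvent against 7.4 and 104 in the shIKKE line with solvent.

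The first comparison asked what 3 h of PMA and ionomycin did in the control line. With stimulation, 14 of 23 measured cytokine genes (34 listed), 13 of 23 NF-κB targets (28) and 9 of 19 activation molecules (24) were at least 2-fold higher. Over all genes these were 1039 of 13717. The recombinase genes RAG1 and RAG2 had lower signals. CRTAM, a surface receptor of activated lymphocytes, read 15.5 with solvent and 2932 with stimulation (log2 6.64). TNFSF14, a TNF family ligand also called LIGHT, read 8.4 and 1303 (log2 5.87), and the chemokine gene CCL4 read 4.8 and 570 (log2 4.95). The lymphotoxin gene LTB went from 352 to 10988 (log2 4.91, and -0.07 by a dimmer probe set), the chemokine gene XCL1 from 7.4 to 379 (log2 4.20) and TNF from 173 to 2442 (log2 3.71). IL2, the T cell growth factor gene, read 4.4 and 245 (log2 3.81), and IFNG read 23.5 and 190 (log2 2.44). The early activation marker CD69 went from 1425 to 14797 (log2 3.36). RAG1 read 1016 with solvent and 80.5 with stimulation (log2 -3.45), RAG2 read 563 and 58.5 (log2 -2.99), and the signalling adaptor gene GAB2 read 399 and 36.0 (log2 -3.04).

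By gene list, 14 of 23 measured cytokines and chemokines were at least 2-fold higher, 1 was lower (IL4, log2 -1.44) and 8 lay within 2-fold, with a median log2 change of 2.18. Of 23 NF-κB targets, 13 were higher, none lower and 10 within 2-fold, with a median of 1.43; RELB (log2 3.45), IER3 (3.08), BCL2A1 (2.84) and CD83 (2.76) were among the largest. The NF-κB inhibitor gene NFKBIA read 1068 and 3854 (log2 1.84). Of 16 NFAT targets, 9 were higher, 1 lower and 6 within 2-fold, with a median of 1.28, while RCAN1, a calcineurin-dependent gene, read 2598 and 1575 (log2 -0.72). Of 18 MAPK feedback regulators, 7 were higher, 1 lower and 10 within 2-fold, with a median of 0.82; the phosphatase genes DUSP5 (log2 3.55) and DUSP2 (2.24) and the Sprouty gene SPRY4 (1.94) were higher and DUSP10 (-1.34) was lower. Of 19 activation and checkpoint molecules, 9 were higher and 10 within 2-fold, with a median of 0.52; besides CD69 these included the receptor genes TNFRSF4 (log2 1.80, and -0.23 by a second, dimmer probe set), IL2RB (1.76) and TNFRSF8 (1.76). The medians of the first 4 of these lists lay at percentile 100 of the matched random lists and that of the activation molecules at 99.9.

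Immediate early transcription factors went both ways in the control line. Of 24 measured members, 9 were at least 2-fold higher, 3 were lower and 12 lay within 2-fold, with a median log2 change of 0.51 (percentile 100). EGR4 (log2 2.39), NR4A3 (2.54) and BHLHE40 (2.44) were higher, and EGR1 read 9953 with solvent and 23198 with stimulation (log2 1.22). FOSB read 1364 with solvent and 272 with stimulation (log2 -2.27) and ATF3 read 1407 and 548 (log2 -1.34), MYC was lower too (log2 -1.43), while EGR3 read 4526 and 4009 (log2 -0.17) and NR4A1 read 747 and 668 (log2 -0.16). Set against the solvent array of the shIKKE line instead, a baseline chosen after the data were seen, 16 members were higher, 1 was lower and the median was 1.63. That baseline moved the median of the NFAT targets to 2.23. Values with that baseline include the difference between the lines besides stimulation.

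Of 29 interferon-stimulated genes, none was at least 2-fold higher in the stimulated control line, 5 were lower and 24 within 2-fold, with a median of -0.61 (percentile 0). IFIT1 read 277 and 55.7 (log2 -2.06), IFI27 read 63.4 and 5.6 (log2 -1.98) and IFIT2 read 312 and 128 (log2 -1.20). With the solvent array of the shIKKE line as baseline the median of this list was -0.11. Of 14 cholesterol synthesis genes, 4 were higher, among them HMGCS1 (log2 1.31) and IDI1 (1.29, and 1.34, 0.14 and -0.43 by 3 dimmer probe sets), and 10 lay within 2-fold. Their median was 0.43 (percentile 99.9), but -0.39 with the other baseline. The latter includes the higher level of these genes in the shIKKE line with solvent (median 0.59). Of 30 cell cycle genes, 29 lay within 2-fold and the cell cycle inhibitor gene CDKN1A was higher (245 and 1312, log2 2.36); the median was -0.26 (percentile 0.39), which lay at percentile 5.21 when each gene was taken as the median of its probe sets. Over all genes, 1039 were at least 2-fold higher and 884 at least 2-fold lower with stimulation, that is 54.0% higher, against 839 and 1121 (42.8% higher) after quantile normalization.

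In the shIKKE line the same treatment gave higher signals of cytokine genes and of early transcription factors, of which 19 of 24 were at least 2-fold higher against 9 of 24 in the control line, a difference that was not tested. EGR4 read 27.5 with solvent and 7756 with stimulation (log2 7.55), NR4A3 read 5.8 and 2493 (log2 6.98), EGR3 read 104 and 9316 (log2 6.30) and EGR1 read 1035 and 18503 (log2 4.14). ARC, a neuronal and immune activity-regulated gene, read 7.8 and 1991 (log2 6.52). CCL4 (log2 7.36), TNFSF14 (7.28), CRTAM (6.58), TNF (6.06), XCL1 (5.89), CD69 (5.51), LTB (4.58) and IL2 (4.50) were all higher. RAG1 read 642 and 87.1 (log2 -2.70), the homeobox gene GSC read 404 and 19.5 (log2 -3.64) and IFIT1 read 262 and 35.9 (log2 -2.47).

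Of 24 immediate early factors, 19 were at least 2-fold higher in the shIKKE line with stimulation, 1 was lower (MYC, log2 -2.21) and 4 lay within 2-fold, with a median of 2.0; FOSB read 7.4 and 302 (log2 3.88). Of 23 cytokines and chemokines, 15 were higher, 1 lower (OSM, 69.6 and 13.6, log2 -1.60) and 7 within 2-fold, with a median of 2.27. Of 16 NFAT targets, 11 were higher, none lower and 5 within 2-fold, with a median of 2.87, and NFATC1 itself went from 1425 to 5371 (log2 1.90). Of 23 NF-κB targets, 15 were higher, 1 lower and 7 within 2-fold, with a median of 1.96; NFKBIA read 817 and 7051 (log2 3.09). Of 18 MAPK feedback regulators, 12 were higher, 1 lower and 5 within 2-fold, with a median of 1.57, and DUSP5 (log2 4.96), DUSP2 (3.87) and SPRY4 (3.68) led them. These 5 medians lay at percentile 100. Of 19 activation molecules, 8 were higher and 11 within 2-fold, with a median of 0.64 (percentile 99.9); the costimulatory receptor gene ICOS read 46.4 and 356 (log2 2.61). Of 18 apoptosis regulators, 5 were higher and 13 within 2-fold, with a median of 0.35 (percentile 100, and 96.6 with the median of each gene's probe sets); GADD45A (log2 2.61), GADD45B (1.79) and MCL1 (1.38) were the largest of these. Interferon-stimulated genes had a median of -0.25 (percentile 0.6), with 1 of 29 higher, 1 lower and 27 within 2-fold. The median of 30 cell cycle genes was -0.27 (percentile 0.46), with 1 higher and 29 within 2-fold, and lay at percentile 25.9 with the median of each gene's probe sets. IKK-related kinases and partners had a median of 0.32 (percentile 99.0), with 2 of 15 higher, TANK (log2 1.29, and 0.70, 0.47 and -0.18 by 3 dimmer probe sets) and TICAM1 (1.08), but it lay at percentile 96.9 after quantile normalization and at 94.8 with no pseudocount. In all, 1417 genes were at least 2-fold higher and 368 lower, that is 79.4% higher, against 1017 and 688 (59.6% higher) after quantile normalization.

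**Figure D2:**
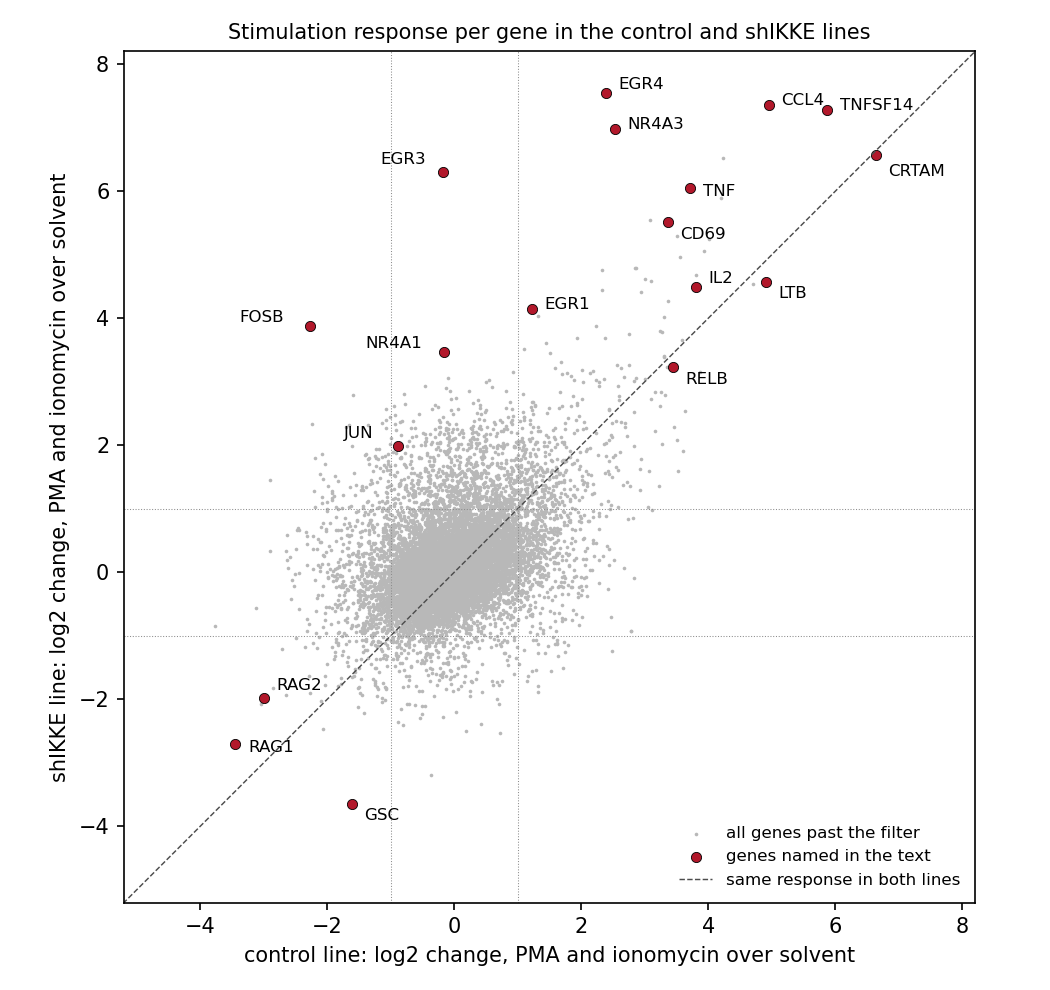
Log2 change of each of 13717 genes with PMA and ionomycin over solvent in the control line (horizontal axis) and in the shIKKE line (vertical axis); grey points are genes, red points are named genes, dotted lines mark 2-fold changes and the dashed line equal responses. CRTAM lay on the line of equal responses (log2 6.64 and 6.58), and FOSB (-2.27 and 3.88) and EGR3 (-0.17 and 6.30) lay far above it.

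The stimulation responses of the lines, which share no array, had 451 genes at least 2-fold higher in both and 106 lower in both. Independent calls would give 107 and 23.7, and calls independent within bins of mean level 188 and 43.1. Across genes, which are not independent replicates, the responses had a Pearson correlation of 0.41 and a Spearman correlation of 0.34, and a Pearson correlation of 0.56 among the genes above the median level. Averaged over the lines, CRTAM rose with an adjusted p of 0.0352 (limma, additive model of line and stimulation; log2 6.61 ± 0.25, SE), and it was the 1 gene of 13717 that passed. With no pseudocount, with no filter, with cyclic loess or with the median of each gene's probe sets, 0 genes passed. The next were LTB (log2 4.74 ± 0.26, SE; adjusted p = 0.0676) and RELB (log2 3.34 ± 0.25, SE; adjusted p = 0.0752). Of the genes named for the largest increases in both lines, ARC (log2 5.37), PLAU (4.63), encoding the protease urokinase, and EGR4 (4.97) did not pass. Nor did those named for the largest decreases, RAG1 (log2 -3.07), GSC (-2.63), GAB2 (-2.56), RAG2 (-2.49), the glycolytic regulator PFKFB4 (-2.34), HYLS1 (-2.29), IFIT1 (-2.26), the Wnt receptor gene FZD2 (-2.08), ZNF488 (-2.07) and the chaperone gene SERPINH1 (-1.96), with adjusted p from 0.0826 to 0.189. At an unadjusted p under 0.05 there were 1887 genes, where chance gives 686. The model has 1 residual degree of freedom and counts any difference between the lines' responses as error. With the error variance allowed to follow the level, 1044 genes passed (639 higher, 405 lower), but that fit takes the error from other genes of the same level and not from the gene itself.

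Adjusted over the list alone, the same model gave more. Of the 23 cytokines and chemokines 14 passed and rose, among them IL2 (log2 4.15 ± 0.29, SE), CXCL8 (4.50 ± 0.36) and CCL1 (3.00 ± 0.26), against 0 over all genes. A second CXCL8 probe set had log2 changes of -0.09 in the control line and 3.89 in the shIKKE line. Of the 23 NF-κB targets 16 rose, adjusted over the list alone, including RELB, CD83 (log2 3.25 ± 0.34) and NFKBIA (2.46 ± 0.38). Of the 24 immediate early factors 12 passed, of which MYC fell by 1.82 on the log2 scale and the others, such as EGR1 (2.68 ± 0.72) and BHLHE40 (2.5 ± 0.25), rose. A second BHLHE40 probe set, whose signals reached 77.6 at most, had log2 changes of 2.42 in the control line and -1.82 in the shIKKE line. Of the 18 MAPK regulators 10 passed and 9 of them rose, led by DUSP5 (4.26 ± 0.41), while ZFP36L2 fell by 1.17. MYC, ZFP36L2 and TNFSF10 are named here after their values were seen. Of the 16 NFAT targets 8 rose, and of the 19 activation molecules 7 rose, led by CD69 (4.44 ± 0.55). Of 23 T cell receptor and proximal signalling genes, the adaptor gene LCP2 rose by 1.53 while RHOH fell by 1.77 (log2 0.29 in the control line by a dim second probe set) and PRKCQ, encoding protein kinase C theta, fell by 1.20, adjusted over the list alone. Single members passed in 6 further lists: IFIT1 fell by 2.26, and CDKN1A (2.70), GADD45A (2.16), HMGCS1 (1.33), the stress gene DDIT3 (2.21) and the granzyme gene GZMB (4.40) rose. No member of any list passed over all genes, since CRTAM is in none of them.

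The next comparison set the shIKKE line against the control line with solvent, which asks what the hairpin line differs in at rest. Of 24 immediate early factors, 14 were at least 2-fold lower in the shIKKE line, 1 higher and 9 within 2-fold, with a median of -1.40 (percentile 0). FOSB read 1364 in the control line and 7.4 in the shIKKE line (log2 -6.01), EGR3 read 4526 and 104 (log2 -5.26), EGR4 read 1129 and 27.5 (log2 -4.78) and EGR1 read 9953 and 1035 (log2 -3.25). Each of the other 2 probe sets of EGR1 had the same direction, with log2 differences of -3.10 and -3.23. NR4A3 (log2 -3.06), NR4A1 (-2.63), IER3 (-2.53), DUSP5 (-2.41), DUSP2 (-1.89) and CD69 (1425 and 428, log2 -1.70) were lower too. Of 2 dimmer EGR4 probe sets, one was lower in the shIKKE line (log2 -2.29) and the other higher (1.24). Of 18 MAPK regulators, 6 were lower and 12 within 2-fold, with a median of -0.52 (percentile 0.03). This comparison and the stimulation response of the control line share the solvent array of the control line, so a high value there enters both with opposite sign.

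Other genes differed at rest as well. CR2, the complement receptor gene better known from B cells, read 962 and 74.0 (log2 -3.47), the protease gene LGMN 1426 and 177 (log2 -2.91), the ectoenzyme gene CD38 125 and 6.0 (log2 -2.79) and the adhesion receptor gene CD2 1976 and 500 (log2 -1.95). RAP1GAP2, a regulator of the GTPase Rap1, read 68.6 and 583 (log2 2.85), the transcription factor gene MAF read 4.2 and 148 (log2 3.15) and the cyclin gene CCND2 read 64.3 and 293 (log2 1.97, and -0.03 by a dimmer probe set). Of 14 cholesterol synthesis genes, 5 were at least 2-fold higher and 9 within 2-fold, with a median of 0.59 (percentile 100); LSS (log2 1.90), HMGCS1 (1.66), SQLE (1.44) and IDI1 (1.31) had the largest differences, with 1.24, -0.03 and -0.22 by 3 dimmer IDI1 probe sets. Of 20 glycolysis genes, 3 were lower, ALDOC (log2 -2.31), ENO2 (-1.42) and SLC2A3 (-1.20), and 17 within 2-fold, with a median of -0.20 (percentile 0.58). Interferon-stimulated genes had a median of -0.33 (percentile 1.41), with 5 of 29 lower, such as IFIT3 (log2 -1.36) and MX2 (-1.37), and 24 within 2-fold. Activation molecules had a median of -0.51 (percentile 0.24, and 13.3 with the median of each gene's probe sets), with 3 of 19 higher, 4 lower and 12 within 2-fold. The median of 30 cell cycle genes was -0.23 (percentile 0.03), with CCND2 higher, 2 lower and 27 within 2-fold. Cytokines (median -0.06), NFAT targets (-0.20) and NF-κB targets (-0.26) lay at percentiles 58.9, 23.0 and 7.09. Over all genes, 596 were at least 2-fold higher and 916 lower in the shIKKE line.

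With stimulation, 12 of 23 cytokines and 8 of 16 NFAT targets were at least 2-fold higher in the shIKKE line than in the control line, and 21 of 24 early factors lay within 2-fold. CXCL8, encoding the chemokine interleukin-8, read 230 in the control line and 1764 in the shIKKE line (log2 2.87), CCL4 read 570 and 2603 (log2 2.16), IL3 read 102 and 410 (log2 1.87), CCL1 read 218 and 773 (log2 1.76) and XCL1 read 379 and 1204 (log2 1.63). TNF read 2442 and 7245 (log2 1.56), GZMB read 527 and 1432 (log2 1.42) and IL2 read 245 and 629 (log2 1.31), whereas IFNG read 190 and 159 (log2 -0.24). Of 23 cytokines and chemokines, 12 were at least 2-fold higher, 1 lower (TNFSF10, log2 -1.05) and 10 within 2-fold, with a median of 1.10. Of 16 NFAT targets, 8 were higher, none lower and 8 within 2-fold, with a median of 1.10; NFATC1 read 2776 and 5371 (log2 0.95) and RCAN1 read 1575 and 1663 (log2 0.08). Both medians lay at percentile 100. All 8 higher NFAT targets are members of other lists too, so this count is not a separate result. CCL4, IL3, FASLG, XCL1, TNF and IL2 are on the cytokine list, and EGR3 and NR4A3 on that of early factors. Of 23 NF-κB targets, 5 were higher and 18 within 2-fold, with a median of 0.23 (percentile 99.2). EGR1 read 23198 and 18503 (log2 -0.33) and CD69 read 14797 and 20144 (log2 0.44), and the 24 early factors had a median of 0.08 (percentile 88.6), with 3 higher and 21 within 2-fold. MAPK regulators (median 0.11), activation molecules (0.17) and interferon-stimulated genes (-0.07) lay at percentiles 84.2, 86.2 and 9.61.

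Cholesterol synthesis genes had a median of 0.71 with stimulation (percentile 100), with 4 of 14 higher and 10 within 2-fold; HMGCS1 read 2432 in the control line and 7964 in the shIKKE line (log2 1.71), and DHCR7 read 567 and 1233 (log2 1.10). Of 17 endoplasmic reticulum stress and heat shock genes, 2 were higher, CHAC1 (log2 1.43) and XBP1 (1.33), and 15 within 2-fold, with a median of 0.55 (percentile 100). Glycolysis genes had a median of -0.25 (percentile 0.01), all 20 within 2-fold. Cell cycle genes had a median of -0.17 (percentile 0.08), with CCND2 higher and 29 within 2-fold. Apoptosis regulators had a median of 0.16 (percentile 99.2, and 70.9 with the median of each gene's probe sets), all 18 within 2-fold. CR2 read 391 and 45.4 (log2 -2.77), RAP1GAP2 read 51.4 and 488 (log2 2.94) and the myosin gene MYO5B read 3.0 and 185 (log2 3.55). Over all genes, 822 were at least 2-fold higher and 325 lower in the shIKKE line, and 1092 of these 1147 were below the median level. Above the median level 20 were higher and 35 lower. After quantile normalization, 681 of all genes were higher and 392 lower.

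The differences between the lines with solvent and with stimulation, which share no array, had 103 genes at least 2-fold higher in the shIKKE line in both treatments and 84 lower in both, where calls independent within bins of mean level would give 106 and 44.5. In opposite directions, 26 genes were at least 2-fold higher with solvent and lower with stimulation, and 102 lower with solvent and higher with stimulation. Among the 6859 genes above the median level, 5 were higher and 16 lower in both, where 0.4 and 1.2 would be expected. Across genes the differences with solvent and with stimulation had a Pearson correlation of 0.12 and a Spearman correlation of 0.14, and a Pearson correlation of 0.25 among the genes above the median level. Large mean differences were those of RAP1GAP2 (log2 2.90 ± 0.25, SE), MYO5B (2.44 ± 0.57), CXCL8 (2.30 ± 0.36) and MAF (2.27 ± 0.47) among the higher, and of CR2 (-3.12 ± 0.30), GSC (-2.28 ± 0.53), CD38 (-2.08 ± 0.41) and LOC154761 (-2.08 ± 0.26) among the lower. The remaining named genes were KCNG4, H4C13, NECTIN1, LARP6, PTGES and the chemokine receptor gene CX3CR1, with means from 1.95 to 2.16, and KIAA0040, LGMN, DIPK2B, the B cell chemokine receptor gene CXCR5, LCAT and NINJ2, with means from -2.02 to -1.89. Of these 20 genes, CX3CR1, LGMN and NINJ2 alone read above the filter level of 56.4 on all 4 arrays, so the means of the others rest in part on signals near background and have no exact rank. A second KIAA0040 probe set was higher in the shIKKE line with stimulation (11.3 and 45.9, log2 1.24). A second NECTIN1 probe set had log2 differences of 0.08 with solvent and 0.36 with stimulation, against 1.24 and 2.97 by the one used. No gene passed for the mean difference (limma, lowest adjusted p = 0.564), with 1000 genes at an unadjusted p under 0.05 where chance gives 686. With the error variance following the level 232 passed (80 higher, 152 lower). Adjusted over the list alone, HMGCS1 (1.68 ± 0.25, SE), SQLE (1.15 ± 0.28) and DHCR7 (1.03 ± 0.25) passed as higher in the shIKKE line among the 14 cholesterol synthesis genes, against 0 over all genes. Adjusted likewise, CXCL8 and CCL1 (1.92 ± 0.26) passed as higher and TNFSF10 as lower (-1.20 ± 0.26) among the cytokines, CXCL8 also among the NF-κB targets, and CCND2 (1.94 ± 0.25) as higher among the cell cycle genes. With solvent the CXCL8 signals were 1.8 and 39.0, below the filter level too, and a second CXCL8 probe set was lower there in the shIKKE line (21.4 and 5.0, log2 -0.89) and higher with stimulation (log2 3.08).

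The last comparison asked whether the response to stimulation differed between the lines, as the response of the shIKKE line minus that of the control line. This difference is signed: a larger response includes a weaker decrease, and a smaller response includes a stronger decrease. The response was at least 2-fold larger in the shIKKE line for 14 of 24 early factors and 10 of 16 NFAT targets. The difference was 6.47 for EGR3, 6.15 for FOSB, 5.16 for EGR4, 4.44 for NR4A3, 3.62 for NR4A1, 2.92 for EGR1 and 2.88 for JUN on the log2 scale, and 2.34 for TNF and 2.15 for CD69. Other probe sets of these genes past the filter had the same sign. Some gave much smaller differences, such as 0.64 and 1.94 for NR4A1 and 0.33 for a dim one of EGR4. CRTAM (-0.06), LTB (-0.33), RELB (-0.22) and IL2RB (-0.15) had nearly equal responses. Of 24 early factors, 14 had a response at least 2-fold larger in the shIKKE line, none smaller and 10 within 2-fold, with a median of 1.62. Of 16 NFAT targets, 10 were larger and 6 within 2-fold, with a median of 1.56. Of 18 MAPK regulators, 10 were larger and 8 within 2-fold, with a median of 1.0, and of 23 NF-κB targets, 10 were larger and 13 within 2-fold, with a median of 0.83. These 4 medians lay at percentile 100. Of 23 cytokines and chemokines, 11 were larger, 1 smaller (OSM, -1.65) and 11 within 2-fold, with a median of 0.99 (percentile 100). OSM fell in the shIKKE line (log2 -1.60) and changed little in the control line (0.05). For the early factors the difference stood beside the high solvent values in the control line: their medians were -1.40 for the shIKKE line over the control line with solvent and 0.08 with stimulation. The same held for the MAPK regulators, with medians of -0.52 and 0.11, and for CD69, at -1.70 and 0.44. For the NFAT targets the corresponding medians were -0.20 and 1.10. That list shares members such as EGR3, NR4A3, NR4A1, TNF and CCL4 with the early factors and the cytokines.

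The other genes with the largest differences were dim. LOC105373418 (4.57), BARX2 (4.38), DHRS3 (4.35) and SLC25A42 (4.0) had larger responses in the shIKKE line, and PARAIL (-3.73), ZNF771 (-3.71), PLEK2 (-3.70), C14orf180 (-3.26), MLC1 (-3.22), CBARP (-3.20), PKD2L1 (-3.17) and NAV1 (-3.10) had smaller ones. The 4 other NAV1 probe sets had differences of the opposite sign (0.05 to 0.98), and the 2 other SLC25A42 probe sets gave -0.10 and 0.57. The highest signal of BARX2 on any array was 133 and that of PLEK2 130. Over all genes, 1559 had a signed response at least 2-fold larger and 641 at least 2-fold smaller in the shIKKE line, that is 70.9% larger, and 64.2% larger after quantile normalization. The larger ones include genes with a decrease in the control line alone, such as ALDOC (log2 -1.65, and 0.13 in the shIKKE line). Of these 2200 genes, 1885 were below the median level. By list, the cell cycle genes (median 0.11) and apoptosis regulators (0.25) lay at percentiles 97.5 and 97.8, with the sign turned when each gene was taken as the median of its probe sets (-0.03 and -0.15). Interferon-stimulated genes (0.25), activation molecules (0.18), IKK-related kinases and partners (-0.19), cholesterol synthesis genes (-0.17), glycolysis genes (-0.04) and endoplasmic reticulum stress and heat shock genes (-0.10) lay between percentiles 6.25 and 88.0. Signs turned here too, such as for the IKK-related list with the median of each gene's probe sets (0.25) and for activation molecules after quantile normalization (-0.02).

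**Figure D3:**
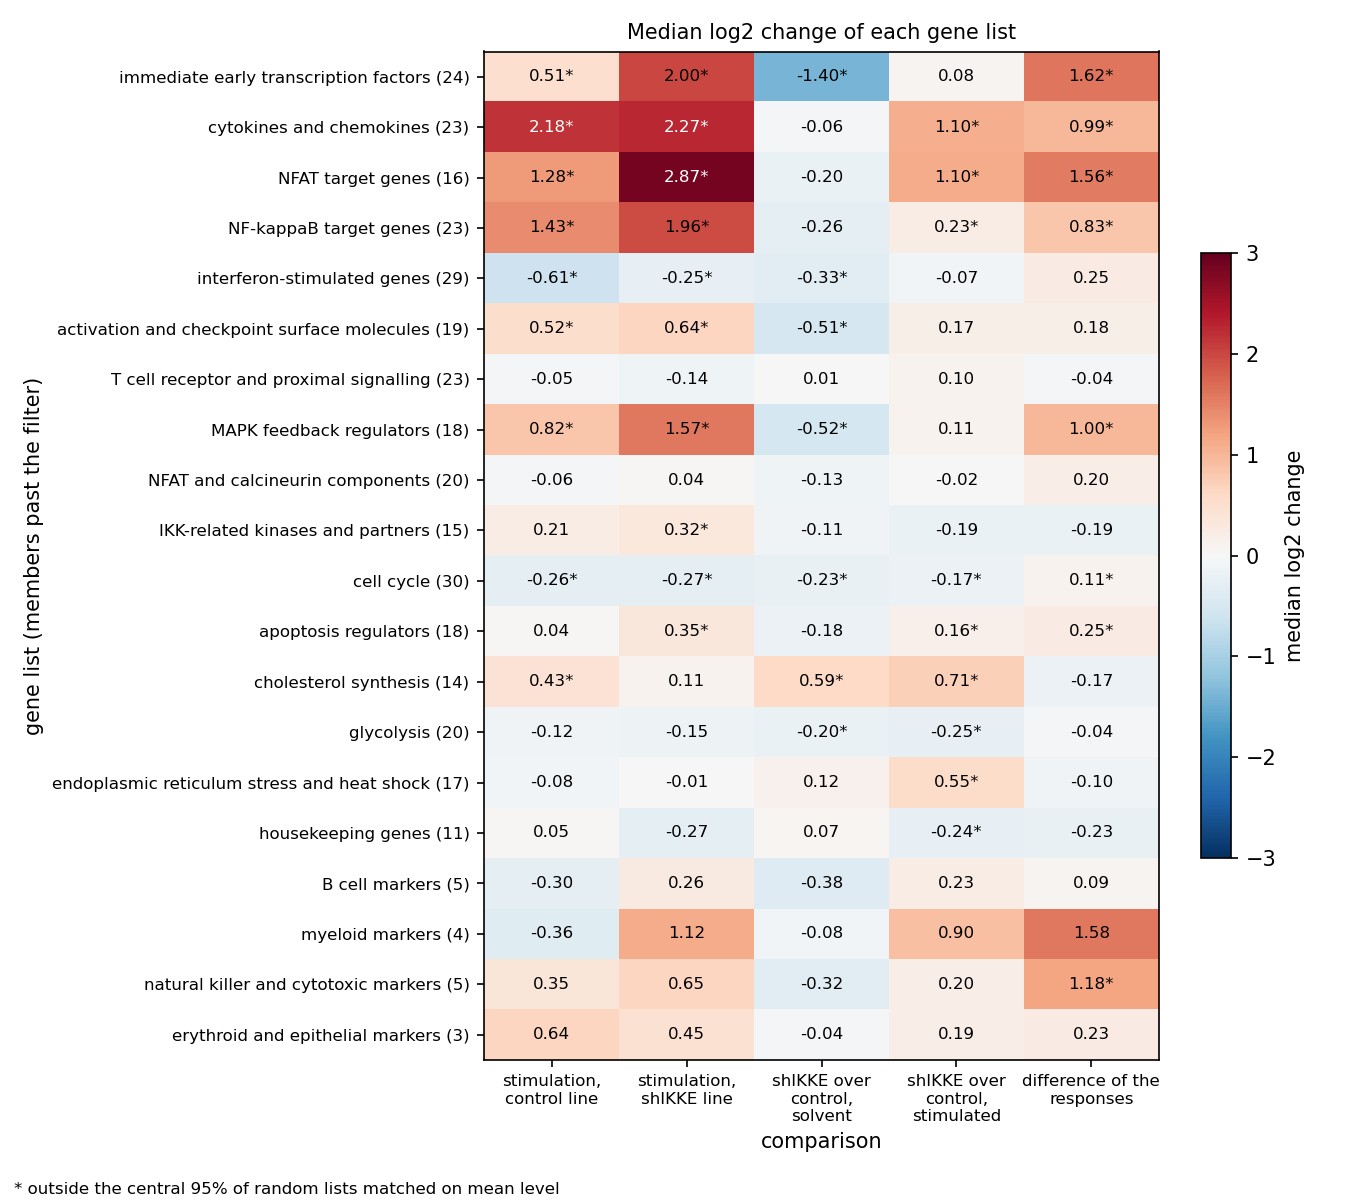
Median log2 change of each of 20 gene lists (down the side, with the number of members measured) in the 5 comparisons (across), coloured from blue (lower) to red (higher); an asterisk marks medians outside the central 95% of 10000 random lists matched on mean level. Early factors had a median of 2.0 with stimulation in the shIKKE line and -1.40 for the shIKKE line over the control line with solvent.

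T cell receptor and proximal signalling genes had medians of -0.05 and -0.14 with stimulation in the control and shIKKE lines, 0.01 and 0.10 for the shIKKE line over the control line with solvent and with stimulation, and -0.04 for the difference of responses, all between percentiles 37.3 and 96.1. NFAT and calcineurin components had medians of -0.06, 0.04, -0.13, -0.02 and 0.20 in the same order, between percentiles 32.6 and 83.5, although NFAT5 read 652 and 1894 (log2 1.52) with stimulation in the control line. Housekeeping genes had medians of 0.05, -0.27, 0.07, -0.24 and -0.23, of which that for the stimulated lines lay at percentile 0.22, and at 8.95 after quantile normalization (median -0.07); quantile normalization turned the sign of the median for stimulation in the control line (-0.003) and for the lines with solvent (-0.01), cyclic loess that for the lines with solvent (-0.06), and the median of each gene's probe sets both (-0.07 and -0.04). ACTB read 33995, 37900, 41592 and 31442 and GAPDH 26025, 29478, 31605 and 24874 in the control line with solvent and with stimulation and in the shIKKE line likewise.

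Among markers of other cell types, 5 B cell markers had medians of -0.30, 0.26, -0.38, 0.23 and 0.09 in that order, at percentiles between 15.0 and 68.5, beside the lower CR2 and CXCR5. The 4 measured myeloid markers had medians of -0.36, 1.12, -0.08, 0.90 and 1.58 at percentiles between 24.9 and 88.0. The 3 erythroid and epithelial markers had medians of 0.64, 0.45, -0.04, 0.19 and 0.23 at percentiles between 43.6 and 87.0. The 5 natural killer and cytotoxic markers had medians of 0.35, 0.65, -0.32, 0.20 and 1.18, of which the difference of responses lay at percentile 99.4, and at 71.2 with the median of each gene's probe sets. Among these GZMB (1.78) and the granzyme gene GZMA (1.5) had the largest differences of responses. PRF1 went the other way (-1.20, and -1.12 by a second probe set). In all, 43 of 100 medians of lists and comparisons lay outside the central range of random lists, where 5 would by chance, and the lists share members. The 5 comparisons are also made from the same 4 arrays, so the 43 are not separate findings. In the simulation, 7 of 100 unchanged lists stood apart. Those lists were drawn at random from genes with independent noise. Genes of a fixed list can vary together between arrays, so neither the 5 nor the 7 is a yardstick for the 43.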

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

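The tests for noise of dim probe sets and for scaling of the dim end were written before their results were seen, and the tests for carry-over, for exchanged labels, for a lower resting level through the knockdown, for array noise and for line differences were chosen after. The results listed first are genes whose stimulation response had opposite directions in the lines, each at least 2-fold; the differences were not tested, since there is 1 array per group. As the log2 response of the shIKKE line minus that of the control line they were 6.15 for FOSB, 4.57 for LOC105373418, 4.38 for BARX2, 4.35 for DHRS3, 4.0 for SLC25A42, 3.05 for ATF3, -3.1 for NAV1, -3.2 for CBARP, -3.22 for MLC1 and -3.73 for PARAIL. All 10 rest on 1 probe set each, and 7 of the genes have no other past the filter. For the rest, a second ATF3 probe set gave 0.28, the 4 other NAV1 probe sets gave 0.048 to 0.977, and the 2 other SLC25A42 probe sets were lower with stimulation in the shIKKE line (-0.63 and -0.71). Of these 10 genes 9 were below the median level. Over all 13717 genes, 126 had such opposite responses, 2 of them above the median level, and in 100 of them the response of the shIKKE line was an increase.

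Of the 24 immediate early factors, 14 were at least 2-fold higher in the control line with solvent than in the shIKKE line with solvent, among them FOS, FOSB, JUN, EGR1, EGR3, NR4A1, ATF3 and IER2, with a median log2 difference of -2.58 for the shIKKE line over the control line. Carry-over of stimulated control RNA into that array is argued against: the array would need a median share of 65.9% (quartiles 27.4 and 107.7) for the 11 of these 14 genes that were at least 2-fold higher in the stimulated control than in the shIKKE line with solvent, but 3.5% for 11 other genes at least 16-fold higher in the stimulated control than in the shIKKE line with solvent (quartiles 0.1 and 7.0), and 4 genes, FOSB, EGR3, NR4A1 and IER5, would need over 100%. Exchanged labels of the control arrays are argued against too, since 94.3% of 70 genes at least 8-fold higher with stimulation in the shIKKE line are higher in the array labelled as stimulated control. A lower resting level of these genes through the knockdown cannot be told apart from a different state of the single control culture, such as handling before lysis, to which early genes respond within minutes. With stimulation the same genes had a median log2 difference of 0.26 between the lines, and no further solvent array of either line was used here.

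Of the 2200 genes whose response differed by at least 2-fold between the lines, 70.9% had the higher signed response in the shIKKE line. A weaker decrease counts as higher here. If scaling that leaves the dim end free were the cause, 45% to 55% was predicted after quantile normalization. If not, at least 60% was predicted. The share was 64.2%, but it cannot decide the question, because probe sets were filtered on the deposited signals. Those that passed only through the stimulated shIKKE array, which had the highest median signal (69.1), stayed in. Noise of dim probe sets cannot be told apart from true differences for the called genes below the median level. Their other probe sets had the same sign in 64.9% of 573 cases, between the limits of under 60% for noise and at least 75% against it, while for called genes above the median level it was 80.9% of 388. A biological difference between the lines' responses stays open and was not tested.

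For differences between the lines seen with solvent and with stimulation, more genes above the median level were shared than independent calls would give. There the genes at least 2-fold apart in the same direction in both treatments were 12.16 times as many as calls independent within bins of level would give on the higher side (95% Poisson interval 3.95 to 28.37) and 13.81 times on the lower side (7.9 to 22.43). These intervals take genes as independent of each other and hold no variation between replicate arrays, since there is 1 array per group. The expected number also takes all genes of a bin as equally likely to be called. A few variable probe sets called in both treatments would raise the ratio too, so array noise is not excluded for these genes. Below the median level the ratio was 0.93 on the higher side (0.75 to 1.13), where array noise fits, and 1.57 on the lower side (1.22 to 1.99), above the number independent calls give but between the limits of 1.5 and 2, so that noise cannot be told apart from line differences there. Line differences unrelated to the loss of IKBKE, such as those that arise when cells are selected, cannot be told apart from an effect of the hairpin, because there is 1 line of each kind. The differences stand beside an IKBKE log2 difference of -1.03 with stimulation, where a second IKBKE probe set gave -0.14.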

How the results depend on the processing

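All alternatives were planned before the data were examined except the other baseline, which was chosen after seeing the data. Of 101 alternatives of 11 results, 55 kept the result within its limit and 46 moved it. Counts of genes at least 2-fold apart are given in the order stimulation in the control line, stimulation in the shIKKE line, the lines with solvent, the lines with stimulation, and the difference of responses (1923, 1785, 1512, 1147 and 2200). They were 976, 819, 636, 366 and 1160 with the pseudocount at the median of all signals, 3028, 2996, 2693, 2264 and 4081 with no filter, and 804, 464, 488, 127 and 534 with the filter at the 75th percentile. By construction they were more at 1.5-fold (4596, 3840, 3910, 2680 and 4736) and fewer at 3-fold (601, 722, 448, 425 and 913). Quantile normalization kept 76.9% to 92.9% of the called genes and cyclic loess 75.4% to 96.3%. For the average effect of stimulation, with 1 gene passing, 0 passed with no pseudocount, 0 with no filter, 0 with cyclic loess and 0 with the median of the gene's probe sets, 573 with the pseudocount at the median of all signals, 577 with the filter at the 75th percentile, 1044 with the intensity trend and 49 at an adjusted p of 0.1. For the average difference of the lines, with 0 passing, 39 passed with the pseudocount at the median of all signals, 49 with the filter at the 75th percentile and 232 with the intensity trend. The IKBKE difference was -0.244 with solvent and -0.587 with stimulation with the median of the gene's probe sets. The correlation of the responses (0.407) was 0.321 with no pseudocount, 0.491 with the pseudocount at the median, 0.297 with no filter and 0.626 with the filter at the 75th percentile; that of the line differences (0.125) was 0.089, 0.174, 0.088 and 0.253. For the list medians, 3 that stood apart turned sign. With the median of the gene's probe sets the difference of responses was -0.028 for cell cycle and -0.153 for apoptosis regulators. The stimulated control array over the solvent array of the shIKKE line gave -0.388 for cholesterol synthesis, against 0.426 for stimulation in the control line. That contrast includes the difference between the lines, and with solvent these genes were higher in the shIKKE line (median 0.593). Where no construction shows it, the cause was not tested. Of 43 list medians that stood apart, 33 did so with no pseudocount, quantile normalization, cyclic loess and the median of the gene's probe sets alike; the other baseline is not in this count, and the cholesterol synthesis median it turned is among the 33. Leaving out an array gives no further value: a group has 1 array, and 3 of the 4 arrays leave the additive model 0 residual degrees of freedom. No paired analysis by replicate was possible because the groups share 1 replicate number only; the additive model already compares stimulated with solvent arrays within each line. Signal over background limits the dim genes: in the lines with stimulation 1092 of 1147 called genes were below the median level.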

Other observations

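Of 17 endoplasmic reticulum stress and heat shock genes, 4 were at least 2-fold higher in the shIKKE line with solvent, 1 was lower and 12 lay within 2-fold, with a median log2 difference of 0.12 that did not stand apart (percentile 82.1). The members named by the rule went both ways. CALR, encoding calreticulin, read 5203 in the control line and 11420 in the shIKKE line, HSPA5, encoding BiP, 10521 and 23685, and SDF2L1, a partner of BiP, 2022 and 5319. CHAC1, a glutathione-degrading enzyme gene of the stress response, was lower, and DNAJB9, a co-chaperone of BiP, read 1420 and 1290. With stimulation the log2 differences were 0.92 for CALR, 0.40 for HSPA5 and 0.69 for SDF2L1. None of these 3 passed as an average over the treatments (limma, adjusted p 0.572 to 0.677). With the error variance following the level, 5 of the 17 passed over all genes, all higher in the shIKKE line and these 3 among them.

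TNFRSF8, encoding the TNF receptor family member CD30, had at rest in the shIKKE line a level near that of the stimulated control line. It read 276 with solvent and 965 with stimulation in the control line, and 890 and 1020 in the shIKKE line. TNFRSF4, encoding OX40, read 163 and 601, and 491 and 907 by its brighter probe set, but 80.7 and 66.6, and 67.4 and 73.0 by a second one. CD69 was lower at rest in the shIKKE line (1425 and 428). The differences were not tested, since there is 1 array per group.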
